A study of Rattus norvegicus with 6 samples.

How the data were processed

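Total RNA of 6 BMMSC samples (3 Wistar, 3 GK) was labelled with Cy3, per the labels, and hybridised to one array each. Groups and replicate numbers were taken from the sample titles. The scanner values are linear intensity per spot that the authors obtained with Agilent Feature Extraction 11.0.1.1, per the file headers, and the processed signal is background-corrected by that software and not normalised between arrays. The header names an older rat build, and no coordinate is printed here. The log2 values of the authors' deposited series table cover 38620 probes, and how they were normalised is not given in the sources used here. Each of its columns correlated best with its own array (Spearman's rho 0.992 to 0.995 across probes), and the column medians were 4.84 in all 6. That table served as an alternative only. A rank correlation gives its order and direction but not its scale. Its GK minus Wistar differences correlated with the log2 differences from the scanner values at Pearson's r 0.986 over 27821 probes. How its values were centred stays unknown.

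Control spots and spots with an outlier flag were left out, between 0.356% and 1.21% of the spots of an array, and spots of the same probe were averaged. Values are log2 of the processed signal minus the array's 75th percentile. A probe was tested when it was well above background on at least 3 of the 6 arrays and measured on at least 2 arrays of each group, which left 27921 of 38804. Each array had between 25282 and 29998 probes well above background. GK was compared with Wistar with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), two-sided, with Benjamini-Hochberg adjustment over all probes tested. A probe well above background on no array of a group has only a bound: the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal well above background and the probe's own signal. The procedure was tested on simulated data for the comparison of 3 GK with 3 Wistar arrays over 27595 probes with 50 changed at each size. It recovered 4% of 2-fold, 48% of 4-fold, 78% of 8-fold and 86% of 16-fold changes, with 2 calls among unchanged probes. The simulated values were independent normal draws with each probe's mean and within-group SD. They held no outlying array and no correlation between probes or within a slide, so the 2 calls give no error rate for the real arrays.

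Probes were named only through an accession in the files matched to the RefSeq gene table (assembly GRCr8). Of 50 catalogue probes, with 10 spots each, 30 matched 1 gene, and the other 38774 probes have no name here. The rule fixed before the data were examined named transglutaminase 2, up to 12 genes each way with an adjusted p under 0.05, and members of fixed gene lists. It yielded Enpp1, Ldha and Map2, since no probe that passed has a name; the other genes are named outside the rule, from all matched probes. Of 40 gene lists fixed in advance, 3 had a member with a named probe (1 each, in the osteoblast, glycolysis and hypoxia, and neural lists), and no list reached the 5 tested members needed for a test, so no list was tested.

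Alternatives fixed before the data were examined were 3 other normalisations, the authors' table, other filters, a variance trend, array weights, the replicate number or the slide as a block, and each array left out. Chosen after seeing the data were normexp on the median signals, since the planned mean signal is not a column of the files, the slide as a random block, and the fit within the shared slide.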

Results

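RNA was measured in rat bone marrow mesenchymal stromal cells (BMMSCs), adherent marrow cells that can form osteoblasts, after 7 days in osteogenic medium. The cells came from Wistar rats, the normal control, or from GK rats, the strain the labels use for type 2 diabetes, with 3 arrays per group. Each sample was hybridised with a single dye to an Agilent array whose 38804 probes are not controls. The labels number the samples of a group as replicates and do not say whether each came from its own animal, so the p-values measure only the spread between these samples. Between 65.2% (Wistar replicate 1) and 77.3% (GK replicate 1) of the probes were well above background on an array, no spot was saturated, and the 75th percentile of the processed signal lay between 171.6 and 234.8. The number of arrays limits the precision. The series title concerns transglutaminase 2 in diabetic bone regeneration. The comparison here asks which transcripts differed between GK and Wistar cells after 7 days in osteogenic medium. Diabetes cannot be told apart from other differences between the strains. All samples were induced, so no effect of induction is measured.

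Enpp1, which makes the mineralisation inhibitor pyrophosphate and is the member of the osteoblast differentiation list with a named probe, had a mean log2 level relative to the array's 75th percentile of 4.44 ± 1.53 (SD, n = 3) in GK cells and 3.23 ± 0.56 (SD, n = 3) in Wistar cells. This 2.31-fold higher mean did not pass the test (limma adjusted p = 0.556). GK replicates 1 and 2 read 5.38 and 5.26, GK replicate 3 read 2.68, and the Wistar arrays read 3.60, 3.51 and 2.58. Without GK replicate 3 the log2 difference was 2.09 with a limma adjusted p of 0.0427, while the adjusted p lay between 0.202 and 0.827 in every other setting that was run. The difference was 0.74 without GK replicate 1, 0.80 without GK replicate 2 and 1.46 with the slide as a random block. With the slide as a fixed block it was 2.15. That value rests on GK replicate 1 alone against the Wistar arrays, since GK replicates 2 and 3 had a slide to themselves. Ldha, a lactate dehydrogenase subunit and the member of the glycolysis and hypoxia list with a named probe, was at 3.61 ± 0.21 in GK and 3.24 ± 0.12 in Wistar cells (SD, n = 3 each), a log2 difference of 0.37 with an adjusted p of 0.507. Map2, a neuronal microtubule protein in the neural marker list, was well above background on 2 of the 6 arrays and was not tested.

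Slc28a2, a nucleoside transporter, had the widest spread among the named genes. Its log2 level was 2.33 ± 3.88 in GK and 5.29 ± 1.38 in Wistar cells (SD, n = 3 each), a difference of -2.96 that did not pass (limma adjusted p = 0.561). GK replicates 1 and 2 read -0.96 and 1.34 and GK replicate 3 read 6.62, above all 3 Wistar arrays, which read 3.77, 5.64 and 6.46. The difference was -5.10 without GK replicate 3 (limma adjusted p = 0.0561), -1.31 without GK replicate 1 and -3.84 with the slide as a random block. With the slide as a fixed block it was -6.25, from GK replicate 1 alone against the Wistar arrays. The difference did not pass in any setting that was run. Fgf2, a fibroblast growth factor, differed by 0.75 (standard error 0.33, adjusted p = 0.415), and the translation factor Eif4b by 0.38 (standard error 0.24, adjusted p = 0.567). N-cadherin, encoded by Cdh2, differed by -0.48 (standard error 0.30, adjusted p = 0.567). None of these 3 passed in any setting that was run, and their sizes moved. Over all settings Fgf2 lay between 0.40 and 1.17. Eif4b lay between 0.08 and 0.58, with 0.20 without Wistar replicate 1 and 0.58 without Wistar replicate 2. Cdh2 lay between -0.78 and -0.33, with -0.77 without GK replicate 3. The 1.17 and the -0.78 came with the slide as a fixed block, from GK replicate 1 alone against the Wistar arrays. The 0.40 and the 0.08 came with array weights, whose estimation stopped before it converged. The same levels are plotted per array.

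**Figure D1:**
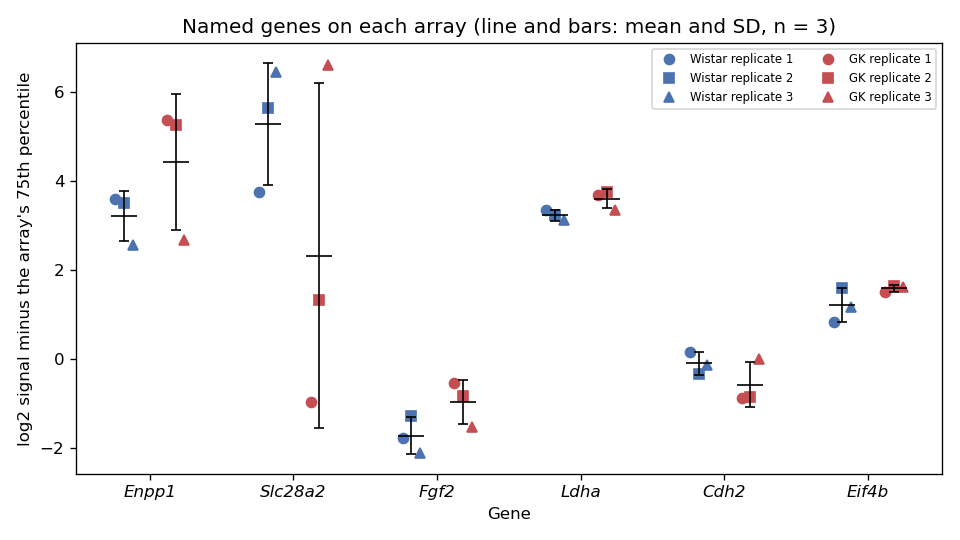
Levels of 6 named genes on each array, as log2 signal minus the array's 75th percentile (vertical axis), with a symbol per replicate, blue for Wistar and red for GK; black lines and bars are the mean and SD of 3 arrays. GK replicate 3 lies apart from the other GK arrays for Enpp1 (2.68 against 5.38 and 5.26) and Slc28a2 (6.62 against -0.96 and 1.34).

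Across the 23 tested genes with a name, 17 had a higher and 6 a lower mean in GK cells. Of all 40 catalogue probes tested, 32 were higher, while the median log2 difference over all tested probes of the array was -0.0039. Among the 23 genes limma called 0 at an adjusted p under 0.05, and 0 also at an unadjusted p under 0.05. Adjusted over these 23 genes alone, the smallest p was 0.506. The median half-width of their 95% intervals was 0.60 on the log2 scale, or 1.51-fold. The median SD between arrays of a group was 0.30, against 0.09 between the 10 spots of a probe on an array. A further probe matched LOC108352165, annotated as a long noncoding RNA, and differed by 0.89 (standard error 0.32). Its unadjusted p was 0.0278 in limma and its adjusted p 0.326. The difference was 0.29 with normexp, 0.52 with array weights and 0.79 with the slide as a random block. With the slide as a fixed block it was 0.51, from GK replicate 1 alone against the Wistar arrays. Lhcgr, Nlrp3, P2rx2 and Gdnf, which encode a gonadotropin receptor, an inflammasome sensor, an ATP-gated channel and a neurotrophic factor, were well above background on 0 of the 6 arrays. Transglutaminase 2 was not analysed here, because no probe could be paired with its name from the tables used.

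Over all 27921 probes tested, limma called 100 at an adjusted p under 0.05, of which 55 were higher and 45 lower in GK cells. This balance turned in some settings, with 284 higher and 380 lower without GK replicate 3 and 458 and 567 with array weights. Among probes well above background on all 6 arrays it was 27 and 35. With the slide as a fixed block the higher probes stayed the larger part. All 100 had a fitted difference of at least 2-fold, and their median absolute log2 difference was 2.68. In 27 of the higher probes no Wistar array, and in 11 of the lower probes no GK array, was well above background, so these 38 have only a bound. Their median bound was at least 3.32-fold, 13 of the bounds were under 2-fold, 1 of these was under 1 and so gives no fold, and with bounds in place of fitted values the median over all 100 was 2.12 on the log2 scale, or 4.35-fold, and 87 probes were at least 2-fold apart. The p-values of the 38 also rest on dim-group signals that were not well above background. These 38 met the filter through the bright group alone. Only 56 of the 100 were well above background on all 6 arrays. The count of probes that passed was 31, 45 and 31 without Wistar replicates 1, 2 and 3. It was 54, 34 and 664 without GK replicates 1, 2 and 3. Wistar replicates 1 to 3 and GK replicate 1 shared a slide and GK replicates 2 and 3 another: 7 probes passed with the slide as a fixed block, 23 within the shared slide (GK replicate 1 against 3 Wistar arrays, assumed to vary alike), 65 with the slide as a random block, and the second slide holds GK arrays only.

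The files do not pair these probes with gene names, so 4 are given by ID, chosen after their values were seen as the 2 largest differences each way among the probes that passed and were well above background on all 6 arrays. ASRN6AP1B100005015V3 was at 4.07 ± 0.40 in GK and -1.52 ± 0.46 in Wistar cells (SD, n = 3 each), 48.2-fold higher (limma adjusted p = 0.00208). ASRN6AP1B100074199V3 was 31.0-fold higher in GK cells (adjusted p = 0.00203). ASRN6AP1B100062991V3 was at -3.37 ± 0.57 in GK and 1.95 ± 0.76 in Wistar cells (SD, n = 3 each), 40.001-fold higher in Wistar (limma adjusted p = 0.00843), and ASRN6AP1B100012757V3 was 17.8-fold higher in Wistar (adjusted p = 0.00667).

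**Figure D2:**
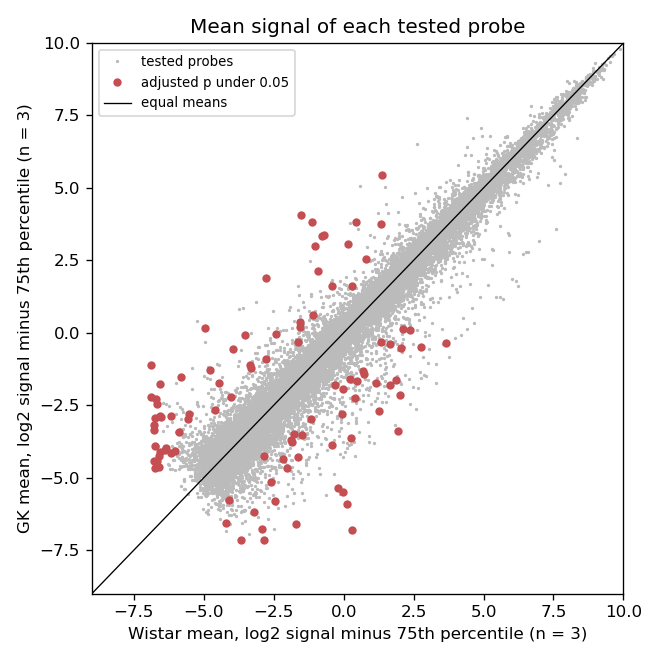
Mean level of each of 27921 tested probes in Wistar (horizontal axis) and GK cells (vertical axis), as log2 signal minus the array's 75th percentile over 3 arrays each; the line marks equal means. Red points are the 100 probes with an adjusted p under 0.05, of which 55 lie above and 45 below the line.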

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

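The normexp, random-block and within-slide fits were chosen after seeing the data. The count of 100 probes at an adjusted p under 0.05 lay within 1.5 times of that value under every other normalisation, filter and variance model that was run, apart from the filter to probes well above background on all 6 arrays (62 probes, with fewer tested). It was 7 with the slide as a fixed block, 23 within the shared slide, 65 with the slide as a random block and 1025 with array weights, whose estimation stopped before it converged. Leaving out each array gave 31 to 664, the highest without GK replicate 3. For at least 2-fold the counts were the same, except 829 with array weights and 66 with normexp. Similar counts did not mean the same probes. Of the 100, 53 passed with normexp, 68 without the filter on dim probes, 81 with the authors' table and 97 with outlier-flagged spots kept. The replicate number as a block gave 77 probes, 53 of them among the 100. The main fit did not pair samples by number, since the labels do not say that the numbers mark a shared batch. Deviations from group means correlated at 0.01, 0.10 and 0.42 for same-numbered arrays of the groups. For differently numbered arrays of the groups they correlated at -0.54 to 0.46. All 100 probes kept their direction wherever they were tested. In the main fit the groups did not overlap for any of the 100. Leaving out arrays or blocking by slide could therefore not reverse a direction, and this adds no support. The cause of the changes in count was not tested.

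Of 454 named-gene values under alternatives, 29 changed sign, all for differences that did not pass, and 1 passed (Enpp1, without GK replicate 3). The slide as a fixed block and the fit within the shared slide both set GK replicate 1 alone against the Wistar arrays. There, Nat1 was at -0.24, Ndfip1 at -0.0051, Odf2l at -0.34, Pdcd10 at -0.062, Pdk3 at 0.058 and Pld1 at 0.039. Pdk3 was also at 0.015 with the median in place of the 75th percentile, 0.023 with outlier spots kept and 0.0066 with the slide as a random block. Magoh was at -0.024 with normexp, and Cyp2e1 at -0.15 with array weights. Leaving out each array gave Dlg4 -0.29 to 0.11, Magoh -0.038 to 0.31, Ndfip1 -0.0075 to 0.19, Pdk3 -0.12 to 0.092, Pld1 -0.22 to 0.11 and Pop7 -0.019 to 0.28. Not run were every alternative for transglutaminase 2 and the gene lists, normexp on the mean signal, the mean over probes of a gene (1 probe each), and the authors' table for named genes, whose probes it does not hold. Signal over background limits 38 of the 100 differences to a bound, and their p-values rest on dim-group signals not well above background.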

Other observations

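The tests in this part were chosen after the results were seen, except both tests on the probes with a sign in their ID. GK replicate 3 lay apart from GK replicates 1 and 2: the latter correlated at 0.982 across probes, GK replicate 3 with them at 0.948 and 0.962, and with Wistar replicate 3 at 0.971. GK replicate 3 also had the highest 75th percentile of the processed signal, 234.8. In the authors' table it had 1 value at the column minimum, against 8706 to 9677 on the other arrays. What these values reflect was not tested. GK replicates 2 and 3 share a slide, so a difference between slides does not account for the distance between these 2 arrays. They correlated at 0.962, below the 0.982 of GK replicates 1 and 2 on different slides. Whether the slide adds to the distance of GK replicate 3 from GK replicate 1 stays open. The split that follows the slides separated 103 probes by at least 2-fold. The median was 20 and the highest 165 over the 13 other splits of 2 arrays against 4. These leave out GK replicates 1 and 2 against the rest (643), which is the pattern itself. This comparison replaced one with the 643 after the values were seen. A Wistar culture under the GK label stays open. At a gap of at least 8-fold, 24 probes parted all GK from all Wistar arrays. With Wistar replicate 1, 2 or 3 in place of GK replicate 3, the counts were 10, 3 and 0. At the same gap, 90 probes parted GK replicates 1 and 2 from the rest, with GK replicate 3 on the Wistar side. Further, 1 array among 4 cannot give a share under 0.25. That criterion replaced a binomial test over probes after the values were seen, since probes are not independent. A different share of another cell type cannot be told apart from a difference between animals, since no fixed cell type list had more than 1 member with a named probe. A difference between animals was not tested.

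The real grouping gave 100 probes at an adjusted p under 0.05, all at least 2-fold, and the highest of the other 9 splits of the arrays gave 6 on both counts; the real split was the 1 of 10 with as many, and 10 splits are too few for a share under 0.05. Looser counts stood out less: 3518 probes had an unadjusted p under 0.05 in limma, against 3035 for Wistar replicates 2 and 3 with GK replicate 1 against the rest, and that split left 5490 probes (19.7%) with no overlap between its groups, more than the 5195 (18.6%) of the real one, where the chance share is 10%. Sequence variants under the probes that weaken binding in GK rats may account for part of the 45 probes that were lower in GK cells, and variants that weaken binding in Wistar rats for part of the 55 that were higher; both stay open because probe sequences were not used. A difference in expression between the strains was not tested separately from strain sequence.

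A set of probes has IDs that begin with uc and carry a plus or minus sign, which the files do not explain. Among those with a minus sign 42 of 203 tested (20.7%) had an unadjusted p under 0.05 in limma, 34 of them lower in GK cells. With a plus sign it was 13 of 182 (7.14%), 9 of them lower, and over all tested probes of the array 12.6%. Most tested probes of either sign were lower (137 and 113). So were 1713 of 2927 probes with IDs that begin with ASRNV2 and 1295 of 2166 with ASRN6LNC1A, but only 10780 of 22343 with ASRN6AP1B. These sets also differed in median level: -3.18 for uc, -2.75 for ASRNV2, -2.38 for ASRN6LNC1A and -1.06 for ASRN6AP1B. Of 40 catalogue probes, at 1.50, 8 were lower, and of 14 with CUST, at 6.00, 8 were lower. Whether direction followed level was not tested. The 1 uc probe that passed the adjustment has a minus sign and was higher in GK cells, with no Wistar array well above background. The excess of minus-sign over plus-sign probes, 13.5 percentage points, was 13.7 within 5 bins of signal level. This argues against a difference in level as its source. The highest excess in the other 9 splits was 2.27, and the real split was the 1 of 10 with an excess as large; these values met a bound written before the splits were run, but that bound was too lenient, since 10 splits are too few for a share under 0.05, and variation unrelated to the groups stays open. Probes are not independent replicates, and the excess is a hypothesis found in these data.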
